A study of Mus musculus with 15 samples.

How the data were processed

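Total RNA from cultured mouse microglia was labelled with biotin and hybridised to Illumina mouse whole-genome bead arrays, and 15 arrays in 4 groups were analysed. The groups were untreated cells (n = 6) and cells exposed for 24 h to IL-4, to LPS with IFN-γ, or to TGF-β (n = 3 each). The submitters' labels number the arrays within a group without saying whether they came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The arrays came from 3 bead chips, each with 1 array of every treatment and 1, 3 or 2 untreated arrays, and chip was examined as a batch by a block term and within chips, but was no term of the fit behind the values printed.

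The deposited signals are intensity values on a linear scale, the mean bead signal of each of 45281 probes, with no background subtracted and arrays not scaled to each other. Per the file headers, a detection p_value accompanies every signal and compares the probe with the array's negative control beads. A second deposited table holds log2 values. The submitters' processing notes name Partek, and the version and steps are not given in the sources used here. Comparing both tables showed that the authors' log2 values equal the quantile-normalized log2 signals after a chip effect per probe was removed with the group differences kept. The median absolute difference from that model was 2.9e-06, and 99.995% of values lay within 0.001. Because a later fit cannot count the removed chip terms, tests on that table overstate the degrees of freedom; the table served only as an alternative.

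Signals were corrected for background with the neqc method, which infers the negative controls from the detection p, with an offset of 16, followed by quantile normalization and log2 (R 4.3.3, limma 3.58.1). Probes with detection p under 0.01 on at least 3 of 15 arrays were kept (15434). Of these, 13310 carried 1 current gene symbol and 2124 did not; the latter were left out of the comparisons. Where a gene had more than 1 probe (3293 genes), the probe with the highest mean over all arrays stood for it, which left 8561 genes. Between 13601 and 14789 probes per array were above background, with a median raw signal of 130.0 to 153.9. For arrays, the number of replicates limits the precision, and the median standard error of a log2 fold change against untreated was 0.101.

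A linear model with 4 group means was fitted to all 15 arrays with limma (lmFit and eBayes, two-sided moderated statistics). Each treatment was compared with untreated and with each other treatment. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes with adjusted p under 0.05 were called. Fold changes are on the log2 scale with their standard error, and group levels are means ± SD. Where no probe of a gene was above background on any array of 1 group, the fold is given as a lower bound. The bound sets that group at the lowest log2 value of any probe above background on each array. Background subtraction affects sizes: without it, or in the authors' table, log2 fold changes of dim genes are smaller.

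For gene groups, 34 lists (signalling targets, pathways, microglial states and markers of other cell types) were fixed before the data were examined, and 25 with at least 5 measured members were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists of a comparison). Camera with a correlation estimated per list and fry served as alternatives. Which lists to describe in the text was decided after their results were seen. The genes named were fixed by a rule. It took the 10 called genes with the highest and the 10 with the lowest fold change whose treated arrays all lay above, or all below, every untreated array. It also took the 2 highest and 2 lowest members of each described list, up to 6 for lists on which the treatment is known to act, and 16 genes fixed by name. For comparisons between treatments it took the 5 highest and the 5 lowest. Predicted gene models were skipped, which left out 2 among the lowest with LPS/IFN-γ. Genes named outside this rule are marked as chosen after their values were seen.

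Alternatives covered background correction, scaling between arrays, the authors' table, the filter on dim probes, the choice of probe, chip or replicate number as a block, the variance prior, array weights, a 2-fold minimum and leaving out each array. Overlap between responses was set beside simulations without any effect in which 3 treatments share 6 untreated arrays, and beside fits with separate untreated arrays per treatment. The model fit was tested on simulated log2 values with 200 changed genes among 8561, fewer than were called in any comparison. These values were drawn independently for each gene, without chip effects. At 2-fold the fit recovered 95 of 100 genes for IL-4, 95 of 100 for LPS/IFN-γ and 91 of 100 for TGF-β; at 1.5-fold it recovered 81, 79 and 75. False calls made up 7.85%, 5.95% and 4.60% of all calls. Background correction, scaling between arrays and the probe filter were not run on the simulated values, so these rates do not cover those steps. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Genome positions were not used here, since the probes are identified by gene symbol.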

Results

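Gene expression was measured in microglia derived from mouse embryonic stem cells, a cultured counterpart of the resident macrophages of the brain, made here from C57BL/6 stem cells. The study asked how pro- and anti-inflammatory activation states differ in these cells. Cells were kept untreated or exposed for 24 h to 1 of 3 stimuli. Interleukin-4 (IL-4, 100 U/ml) is a type 2 cytokine, lipopolysaccharide (LPS, 500 ng/ml) with interferon-γ (IFN-γ, 20 ng/ml) is a classical pro-inflammatory pair, and transforming growth factor-β (TGF-β, 50 ng/ml) is a regulatory cytokine needed by microglia in the brain. There were 3 arrays per treatment and 6 untreated arrays, although the series text speaks of triplicates. The number of arrays limits the precision of every value.

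Arrays of 1 group resembled each other closely, with Pearson correlations of 0.983 to 0.996 across genes, where genes are not independent replicates. Pairs from different groups reached 0.991 (IL-4 replicate 2 with untreated replicate 4), so this measure alone does not separate the groups. Group membership took up 83.4% of the variance of the 8561 genes, and chip a further 3.9%. LPS/IFN-γ changed the most genes (4770 called), followed by TGF-β (3318) and IL-4 (1024). With chip as a fixed block the counts were 4838, 3374 and 1050. Of the called genes, 97.5%, 98.7% and 99.4% moved in the same direction within all 3 chips. Every named call in the 3 comparisons with untreated (79, 64 and 42 genes) was also made with chip as a block and had the same direction within each chip. The shared direction is no separate evidence against a chip effect, since the genes were called from the same arrays. Of the called genes, 3914, 2915 and 939 had no overlap between treated and untreated arrays, which fixes the direction within each chip.

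**Figure D1:**
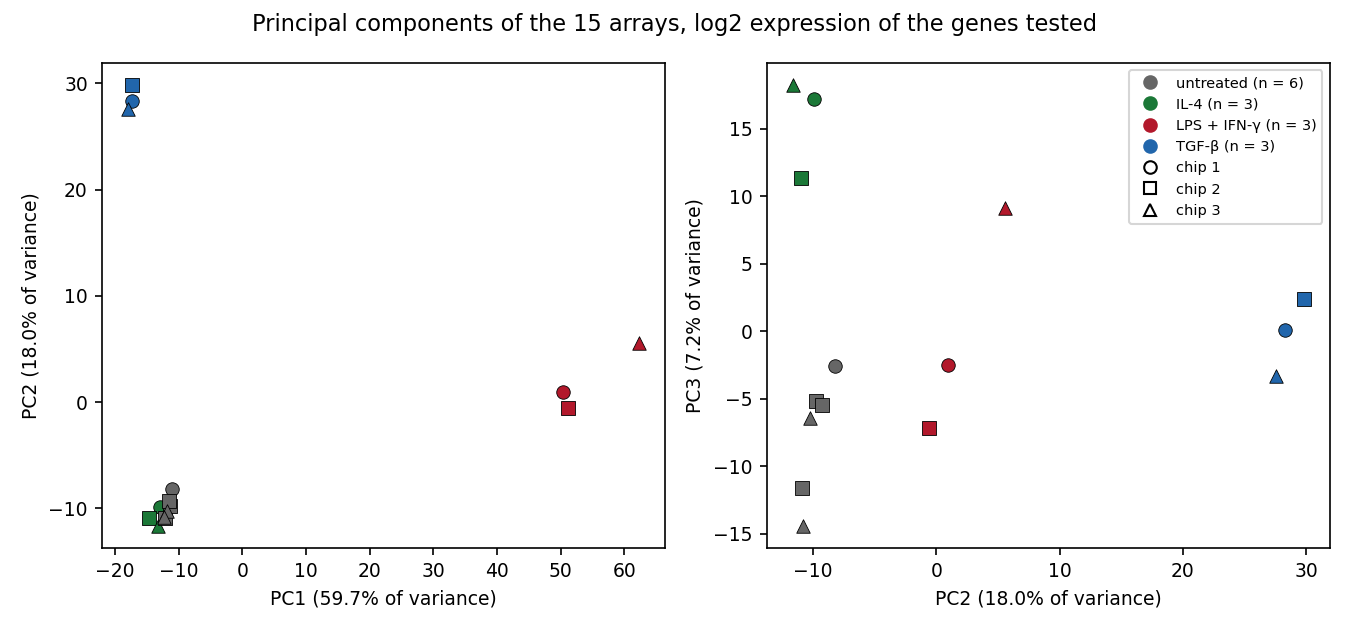
Principal components of the 15 arrays computed from the log2 expression of the genes tested. Each point is 1 array, colour gives the treatment and shape the chip; the components hold 59.7%, 18.0% and 7.2% of the variance.

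IL-4 raised genes of alternative macrophage activation and lowered cell cycle genes. Cish, a feedback inhibitor of cytokine receptor signalling that was above background on 2 of 6 untreated arrays, rose from 5.53 ± 0.23 (SD, n = 6) to 9.10 ± 0.12 (n = 3) on the log2 scale, a log2 fold change of 3.58 ± 0.35 (SE, adjusted p = 8.8e-06). Cish also rose with LPS/IFN-γ, by 2.76, or by 2.06 without LPS/IFN-γ replicate 3 (adjusted p = 3.2e-07). Arg1, the arginase that diverts arginine from nitric oxide synthesis, was below background in untreated cells and rose at least 5.17-fold to 8.07 ± 0.18 (adjusted p = 3.1e-13). The ribonuclease gene Rnase2a rose by 3.40 ± 0.12 and Cd74, the invariant chain of MHC class II, by 2.69 ± 0.13. Further genes among the strongest rises were the lipase gene Lipn (2.55 ± 0.11), the chemokine gene Ccl7 (at least 3.05-fold), Ang2, a ribonuclease of the angiogenin family (2.18 ± 0.13), the collagenase gene Mmp13 (1.96 ± 0.15) and Ms4a7 (1.88 ± 0.16). Ccl7 read 7.17 to 7.42 with IL-4 and 7.41 to 8.62 with LPS/IFN-γ.

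Among genes lowered by IL-4, S100a8, a calcium-binding protein of myeloid cells, fell at least 2.12-fold, from 6.77 ± 0.11 to below background (adjusted p = 2.9e-06), and the sialyltransferase gene St3gal6 at least 2.17-fold. The chemokine genes Ccl3 (log2 fold change -1.20 ± 0.09) and Ccl9 (-1.09 ± 0.10) fell, as did Tlr2, a receptor for bacterial lipoproteins (-1.03 ± 0.12), Wwtr1 (-1.05 ± 0.14), Pid1 (-0.98 ± 0.11) and Klhl6 (-0.96 ± 0.18). The remaining genes of the top 10 in each direction lost their call when single arrays were left out. Sppl2a (1.91 ± 0.53, adjusted p = 0.0287) lost it without each IL-4 array or untreated replicate 2, with adjusted p up to 0.1121. Gpr84 (-1.01 ± 0.28, adjusted p = 0.0283) lost it without each IL-4 array or untreated replicate 5 (up to 0.1011). Hp (-1.14 ± 0.34, adjusted p = 0.0414) lost it in 11 of 15 such fits (up to 0.1390), which left out any IL-4 or untreated array or TGF-β replicate 1 or 3. Without a filter on dim probes the adjusted p of these 3 genes was 0.0543, 0.0533 and 0.0777. For Gpr84 and Hp the fit without LPS/IFN-γ replicate 3, which read 8.27 and 8.48 against 10.04 and 10.71 on replicate 1, gave 5.9e-07 and 1.7e-06.

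In total 1024 genes were called with IL-4, 483 higher and 541 lower, and 54 of them (46 higher, 8 lower) changed at least 2-fold. Over all 8561 genes, 1724 had all 3 treated arrays on 1 side of all 6 untreated arrays, an arrangement that chance gives 2.4% of genes. The count fell to 594 without IL-4 replicate 1 and to 603 without IL-4 replicate 3. Scaling by the median alone gave 345 genes, and 1767 were called in the authors' log2 values. Cyclic loess gave 981, of which 59.3% were higher, against 47.2% with quantile normalization.

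Of 25 gene lists tested, 7 shifted with IL-4, all of them also with chip as a block, and 6 were called with an estimated correlation. Alternative activation genes rose as a group (mean log2 fold change 1.04, 1.00, 1.10 and 0.99 within the chips, adjusted p = 4.7e-14). Of 19 measured members 12 rose, 1 fell and 6 were not called (13 and 1 adjusted over the list alone). Without background correction the list mean was 0.64. Besides Cish, Arg1 and Rnase2a, members that rose were Mgl2, a galactose-binding lectin (1.58 ± 0.08), and Mrc1, the mannose receptor (0.90 ± 0.08), whereas the transglutaminase gene Tgm2 fell (-0.44 ± 0.07, adjusted p = 8.2e-04; 0.0573 with scaling by the median alone). Retnla and Chil3, markers of this state in other mouse macrophages, were above background on 0 of 15 arrays. With LPS/IFN-γ the alternative activation list was not called (adjusted p = 0.4949). Its mean there was 0.25, with 0.01, -0.00 and 0.72 within the chips.

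Cell cycle and replication genes fell with IL-4 (mean -0.35, -0.36, -0.37 and -0.33 within chips, adjusted p = 7.7e-15). Of 27 members 19 fell and 0 rose (24 and 0 adjusted over the list alone), among them Tk1, thymidine kinase (-0.77 ± 0.06), and Aurkb, a mitotic kinase (-0.54 ± 0.07). Of the unfolded protein response list, 6 of 15 members rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0011, chips 0.28, 0.27 and 0.36). The disulphide isomerase Pdia4 rose by 1.12 ± 0.12. Asns, asparagine synthetase, was the member that fell (-0.27 ± 0.07), a call lost without IL-4 replicate 1 (adjusted p = 0.1213) or 2 (0.0624), with scaling by the median alone (0.2055) and on another probe (0.2589). Of 12 NRF2 target genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.0070, chips -0.25, -0.23 and -0.33; adjusted p = 0.0919 with an estimated correlation). The cystine transporter Slc7a11 fell by 0.79 on the log2 scale, but another of its probes gave -0.40 (adjusted p = 0.0876).

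The other 3 called lists shifted little. Disease-associated microglia genes had 3 of 21 higher and 1 lower (7 and 1 adjusted over the list alone; mean 0.19, chips 0.16, 0.25 and 0.15, adjusted p = 0.0127), with rises of Fabp5, a fatty acid carrier (0.90 ± 0.11), and Clec7a, a β-glucan receptor (0.88 ± 0.16; another probe 0.45, adjusted p = 0.0790). Oxidative phosphorylation had 2 of 32 higher and 1 lower, also over the list alone (mean 0.10, chips 0.07, 0.09 and 0.16, adjusted p = 0.0242). Both calls were lost without IL-4 replicate 2 (adjusted p = 0.0538 and 0.0753). Lysosomal genes had 2 of 26 higher, 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0188), with a mean of 0.06 and 0.05, 0.06 and 0.07 within chips. Under scaling by the median alone that mean was -0.01, or 0.10 above the median of all genes. The β-galactosidase gene Glb1 rose by 0.33 ± 0.07 (adjusted p = 0.0039; 0.2666 with scaling by the median alone and 0.1624 on another probe).

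Pro-inflammatory cytokine genes went both ways with IL-4, with 3 of 17 higher, 5 lower and 9 not called (4 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.8021). Their mean was 0.06 (-0.04 without background correction) and their median -0.06. Il1b rose by 1.37 ± 0.14, whereas Tnf fell by 0.81 on the log2 scale. Of 10 MHC class II and costimulation genes only Cd74 and Cd40, a costimulatory receptor (1.19 ± 0.19), were called, and the list was not (adjusted p = 0.3441, mean 0.30, median -0.04). A second Cd40 probe gave 0.24 (adjusted p = 0.6191). Of 16 pattern recognition receptors 3 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.8021, mean -0.03, median 0.02), the latter including Cd14, the LPS co-receptor (-0.69 ± 0.07).

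LPS/IFN-γ raised interferon-induced and inflammatory genes strongly and lowered a list of cholesterol efflux genes and LXR targets. Gbp2, an interferon-induced GTPase of antimicrobial defence, rose at least 579-fold to 14.87 ± 0.09 (n = 3, adjusted p = 4.3e-17), from below background in untreated cells. That bound is for the probe used. The lowest of the 3 Gbp2 probes gave a log2 fold change of 2.67 against IL-4 and 2.59 against TGF-β. The protease inhibitor gene Serpina3f rose at least 244-fold. Gbp3 rose by 7.92 ± 0.11 and the chemokine gene Ccl5 by 7.77 ± 0.10. Cxcl10, a chemokine that attracts T cells, rose at least 124-fold, and Gbp5, Calhm6 and the transcription factor gene Batf2 at least 39.6-fold, 38.1-fold and 34.6-fold. Oasl2, of the oligoadenylate synthetase family, rose by 6.41 ± 0.10. Cxcl9 rose at least 40.3-fold, but its 3 arrays read 9.35, 9.48 and 14.26, and its fitted log2 fold change of 6.36 ± 0.73 was 4.75 without LPS/IFN-γ replicate 3, 7.20 without replicate 1 and 7.14 without replicate 2.

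Genes that fell strongly with LPS/IFN-γ were Ankrd37 (log2 fold change -3.96 ± 0.11, from 9.96 ± 0.12 to 6.00 ± 0.31), Cytip, a regulator of leukocyte adhesion (-3.58 ± 0.18), the kinase gene Srpk3 (-3.04 ± 0.16), the sulphotransferase gene Chst10 (-2.61 ± 0.07), Inafm1 (-2.52 ± 0.08), the transcriptional repressor gene Mxd4 (-2.40 ± 0.14) and Myadml2 (-2.30 ± 0.23). Ankrd37 was above background on 2 of 3 LPS/IFN-γ arrays. Apoc1, an apolipoprotein, fell at least 2.82-fold to below background. Slc37a2, a sugar phosphate transporter, fell by 2.33 on the log2 scale, but its second probe gave -0.40 (adjusted p = 0.0506). Abca9 read 5.21, 5.36 and 4.86 with LPS/IFN-γ against 7.55 to 8.16 in untreated cells, but another probe gave -0.60 (adjusted p = 0.0754).

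LPS/IFN-γ called 4770 genes, 1837 higher and 2933 lower, of which 698 (438 higher, 260 lower) changed at least 2-fold. In 4019 of all 8561 genes the treated and untreated arrays did not overlap (2.4% of genes by chance). The share of higher calls was 38.5% with quantile normalization, 49.9% with cyclic loess (4528 calls, 2259 higher and 2269 lower) and 33.0% with scaling by the median alone (3505 calls, 1156 higher and 2349 lower). LPS/IFN-γ replicate 3 stood apart, with 145 genes at least 2-fold off the other arrays of its group, against 1 to 33 on any other array.

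Of 25 lists 11 shifted with LPS/IFN-γ, all also with chip as a block, and 7 were called with an estimated correlation. All 22 type I interferon-stimulated genes rose, also over the list alone (mean 3.45, chips 3.55, 3.45 and 3.31, adjusted p = 2.9e-25), among them Parp14 (5.98 ± 0.09), Isg15, a ubiquitin-like modifier (5.24 ± 0.15), and Ifit3 (5.19 ± 0.20). Interferon-inducible GTPases and IFN-γ targets had 15 of 16 higher (16 adjusted over the list alone; mean 4.61, chips 4.25, 4.27 and 5.28, adjusted p = 1.1e-16). The gene not called was Irgm1 (0.18 ± 0.07, adjusted p = 0.0502), although another of its probes rose by 4.25. The mean of the last list was higher on chip 3, which holds LPS/IFN-γ replicate 3.

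All 17 pro-inflammatory cytokine and chemokine genes rose with LPS/IFN-γ, also over the list alone (mean 3.33, chips 2.99, 3.15 and 3.80, adjusted p = 7.3e-16). Tnf rose by 4.11 ± 0.12, Cxcl2, a neutrophil chemokine, at least 9.26-fold and Il1b by 0.93 ± 0.14, while Il6 was above background on 0 arrays. The smallest fitted rise, that of Il23a (0.49 ± 0.15), was not called without LPS/IFN-γ replicate 1 (adjusted p = 0.0610). Of 14 inflammatory effector enzymes 13 rose and 1 fell, also over the list alone (mean 2.34, chips 2.26, 2.26 and 2.51, adjusted p = 1.6e-10). Acod1, which makes itaconate, rose by 6.19 ± 0.11, the iron-sequestering lipocalin gene Lcn2 at least 32.0-fold, the acute phase gene Saa3 by 4.34 ± 0.13 and Nos2, the inducible nitric oxide synthase, at least 11.4-fold to 9.21 ± 0.76. Alox5ap, which acts in leukotriene synthesis, fell (-0.40 ± 0.07).

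Antigen presentation genes rose with LPS/IFN-γ. Of 15 MHC class I genes 14 rose, also over the list alone (mean 2.12, chips 2.12, 2.19 and 2.05, adjusted p = 2.3e-15), including the peptide transporter Tap1 (4.11 ± 0.12) and the immunoproteasome subunit Psmb9 (3.59 ± 0.08). Of 10 class II and costimulation genes 9 rose, also over the list alone (mean 1.48, chips 1.23, 1.22 and 1.96, adjusted p = 2.2e-06; adjusted p = 0.1198 with an estimated correlation), among them Cd40 (3.53 ± 0.19) and Cd74 (3.23 ± 0.13). H2-DMa, a class II peptide loader, rose at least 2.07-fold, with a fitted log2 fold change of 1.49 that was 0.95 without LPS/IFN-γ replicate 3. Negative feedback regulators had 16 of 17 higher and 1 lower, also over the list alone (mean 1.98, chips 1.75, 1.73 and 2.46, adjusted p = 1.1e-10). Traf1 rose at least 9.24-fold and Cd274, the ligand of PD-1, by 3.99 ± 0.18, whereas the phosphatase gene Dusp2 fell (-0.97 ± 0.11). With genes below background in 1 group set at their bound, list medians went from 3.07 to 2.77 for type I interferon-stimulated genes, 5.43 to 4.92 for IFN-γ targets, 2.86 to 2.32 for cytokines, 1.75 to 1.38 for effector enzymes, 1.64 to 1.62 for feedback regulators and 1.19 to 0.92 for MHC class II. Without background correction list means were smaller, at 2.32 for type I interferon-stimulated genes, 3.34 for IFN-γ targets, 2.20 for cytokines, 1.74 for effector enzymes, 1.82 for MHC class I, 1.03 for MHC class II, 1.49 for feedback regulators and 0.80, in place of 1.81, for complement.

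Complement genes had 5 of 8 higher and 1 lower with LPS/IFN-γ, also over the list alone (median 2.11, or 1.24 with bounded genes at their bound; chips 1.55, 1.60 and 2.28; adjusted p = 0.0024, and adjusted p = 0.0631 with an estimated correlation). C1qb rose at least 15.4-fold and factor B (Cfb) at least 4.06-fold. The fitted log2 fold change of C1qb, 5.05, was 4.40 without LPS/IFN-γ replicate 3. Glycolysis genes had 6 of 14 higher and 1 lower, also over the list alone (mean 0.31, chips 0.39, 0.36 and 0.22, adjusted p = 0.0290; adjusted p = 0.1886 with an estimated correlation), led by the hexose transporter Slc2a6 (2.00 ± 0.07) and the hexokinase Hk3 (1.26 ± 0.07). NRF2 targets had 6 of 12 higher and 1 lower, also over the list alone (mean 0.37, chips 0.42, 0.49 and 0.23, adjusted p = 0.0366; adjusted p = 0.1738 with an estimated correlation), with Slc7a11 up by 1.63 ± 0.13. The last 2 calls were lost without LPS/IFN-γ replicate 2 (adjusted p = 0.0514 and 0.0603).

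Cholesterol efflux genes and targets of the sterol receptor LXR fell with LPS/IFN-γ, 7 of 9 with 0 higher, also over the list alone (mean -0.91, chips -0.86, -0.90 and -0.95, adjusted p = 0.0017). Besides Apoc1, Apoe, the main lipid carrier of brain tissue, fell from 13.04 ± 0.16 to 11.28 ± 0.18 (-1.76 ± 0.10, adjusted p = 1.7e-09). Abcg1 was not called, though it was called lower without LPS/IFN-γ replicate 3 (-0.37, adjusted p = 0.0122). Of 20 homeostatic microglia genes 3 rose and 9 fell, also over the list alone, but the list was not called (adjusted p = 0.3818); its mean was 0.14 (-0.03 without background correction), its median -0.15, and the test pointed down. Gas6, a ligand of phagocytic receptors, fell (-1.63 ± 0.12), as did the transcription factor gene Mef2c (-0.97 ± 0.14, with -0.14 and adjusted p = 0.6917 on a second probe) and the lipid receptor gene Trem2 (-0.70 ± 0.09). The list also held C1qc, with a fitted log2 fold change of 2.57 (1.81 without LPS/IFN-γ replicate 3). Gpr84, another member, read 10.04, 10.09 and 8.27 with LPS/IFN-γ against 8.04 to 8.23 in untreated cells. The mannose receptor gene Mrc1 fell as well (-1.69 ± 0.08). Cell cycle genes had 5 of 27 higher and 12 lower (6 and 12 adjusted over the list alone) and were not called as a list (adjusted p = 0.3373). Ccne2, a cyclin of the G1/S transition, fell (-2.14 ± 0.12), and Rrm2, a ribonucleotide reductase subunit, gave -0.94 ± 0.09 on the probe used but 0.15 on another (adjusted p = 0.4137).

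**Figure D2:**
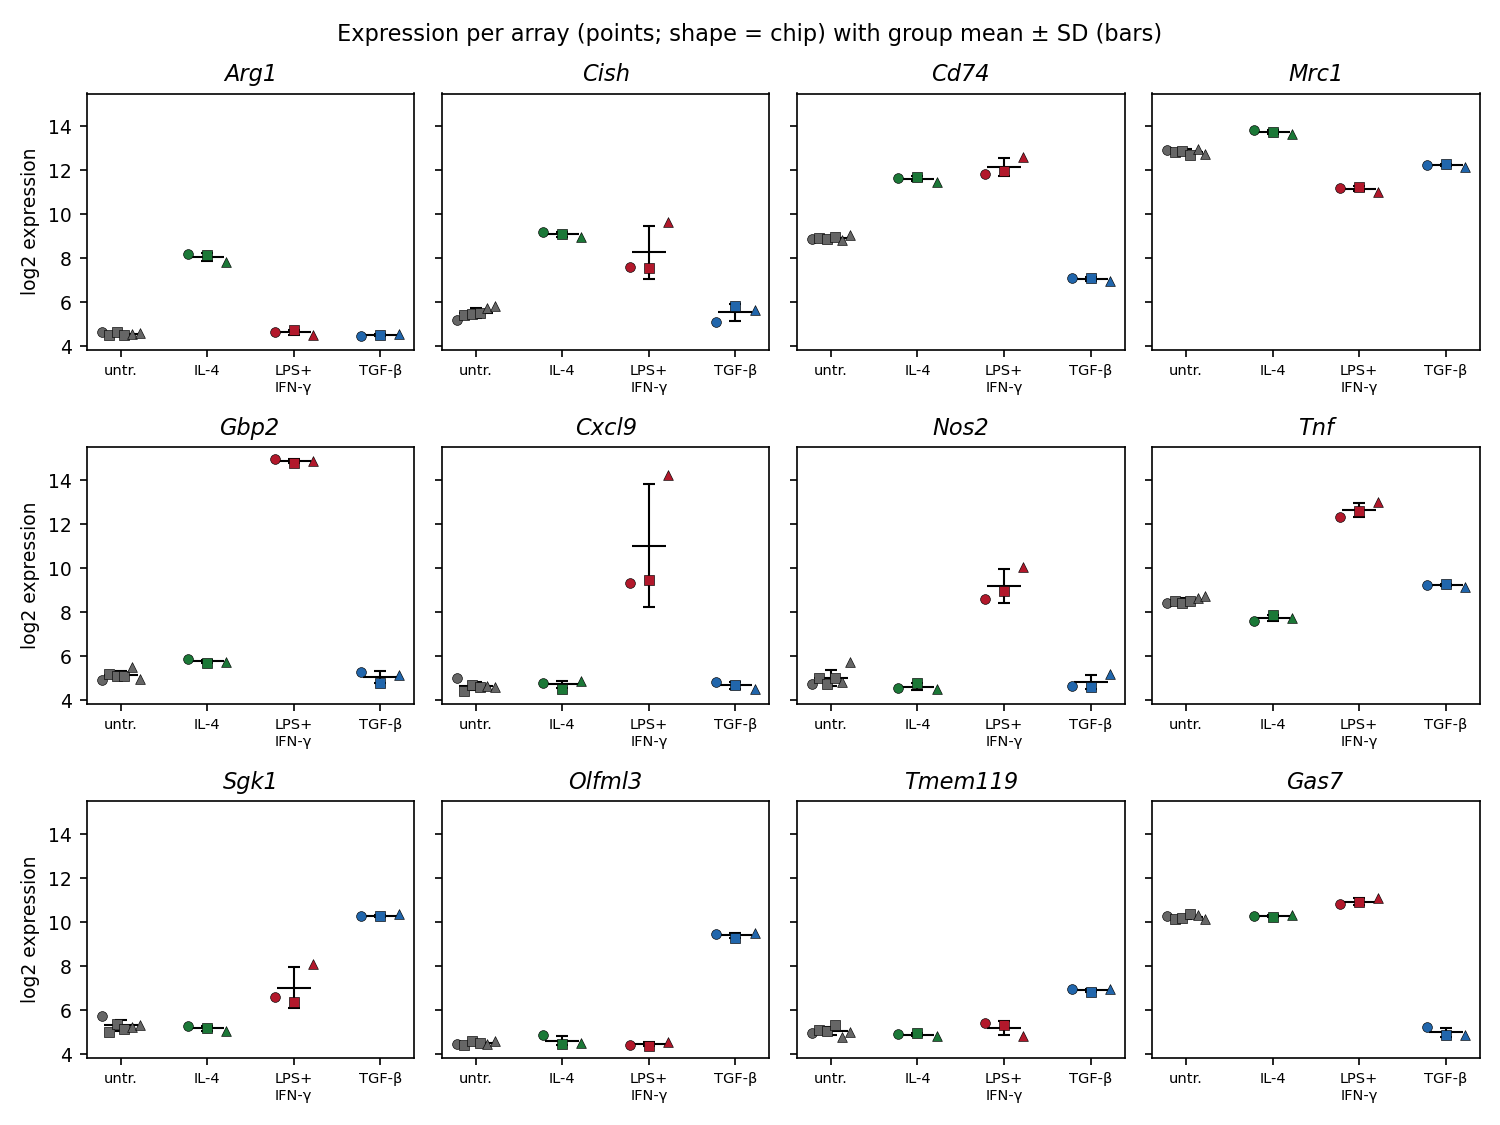
Log2 expression of 12 genes on the 15 arrays by treatment. Points are arrays with the shape giving the chip, and bars are the group mean ± SD; for Cxcl9 with LPS/IFN-γ the 3 arrays read 9.35, 9.48 and 14.26.

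TGF-β raised homeostatic microglia genes and lowered cell cycle genes. Its own target genes rose as a list in camera with the preset correlation but not with an estimated correlation (adjusted p = 0.0701). Sgk1, a serum- and stress-regulated kinase, rose at least 24.5-fold from below background to 10.31 ± 0.05 (n = 3, adjusted p = 2.8e-09), and the microglial gene Olfml3 at least 13.2-fold to 9.42 ± 0.12 (adjusted p = 4.1e-15). Skil, a feedback repressor of Smad proteins, rose by 4.61 ± 0.19, the integrin gene Itgb5 by 4.30 ± 0.16, the myosin gene Myo7a by 3.67 ± 0.14 and the protease gene Prss46 by 3.36 ± 0.16. Rises from below background were those of the cytochrome P450 gene Cyp4f18 (at least 8.71-fold), Bdh2 (at least 7.62-fold), the apolipoprotein gene Apoc4 (at least 7.33-fold) and the serotonin receptor gene Htr2b (at least 5.10-fold).

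Several falls with TGF-β ended below background and are lower bounds that cannot be ranked. Gas7 fell from 10.25 ± 0.09 to below background, at least 23.4-fold (adjusted p = 3.3e-15). The kallikrein gene Klk1b11 fell at least 6.51-fold, the alcohol dehydrogenase gene Adh7 at least 4.36-fold and St3gal6 at least 2.14-fold. Properdin (Cfp), an activator of complement, fell (-2.76 ± 0.09), as did Ccl9 (-2.39 ± 0.11), the transporter gene Slc10a6 (-1.93 ± 0.11), Ifitm6 (-1.82 ± 0.12) and Mthfd2, an enzyme of mitochondrial folate metabolism (-1.75 ± 0.07). Cd74 gave -1.86 ± 0.13, with -2.08 and -0.32 (adjusted p = 0.1186) as the extremes of its 3 probes. TGF-β called 3318 genes, 1689 higher and 1629 lower, of which 235 (172 higher, 63 lower) changed at least 2-fold; in 3315 of all 8561 genes the arrays did not overlap (2.4% by chance). Under scaling by the median alone 2595 genes were called, 20.2% of them higher against 50.9%, and the median of all genes then lay at -0.191.

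Of 25 lists 8 shifted with TGF-β, all also with chip as a block, and 6 were called with an estimated correlation. Of 19 TGF-β and Smad target genes 15 rose and 0 fell, also over the list alone (mean 0.93, chips 0.86, 0.88 and 1.01, adjusted p = 1.8e-06; adjusted p = 0.0701 with an estimated correlation). Besides Skil, Id2, an inhibitor of differentiation factors (1.93 ± 0.35), and Ski (1.36 ± 0.09) rose. Smad7, a feedback inhibitor, was above background on 0 arrays. Of 20 homeostatic microglia genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; mean 0.84, chips 0.84, 0.84 and 0.82, adjusted p = 1.8e-06). Tmem119, a microglial surface marker, rose at least 2.34-fold to 6.92 ± 0.07, the complement gene C1qc at least 1.72-fold, the fractalkine receptor gene Cx3cr1 at least 1.24-fold and Gpr84 by 1.40 ± 0.28. C1qc and Gpr84 were also higher with LPS/IFN-γ than in untreated cells. Sall1, a transcription factor of microglial identity, gave -0.24 ± 0.17 (adjusted p = 0.2765), and P2ry12 was above background on 0 arrays.

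Cell cycle genes fell with TGF-β, 23 of 27 with 0 higher, also over the list alone (mean -0.53, chips -0.49, -0.53 and -0.56, adjusted p = 6.6e-12), including the mitotic kinase Aurka (-0.95 ± 0.07) and Cdc20 (-0.85 ± 0.07). Cholesterol efflux and LXR targets rose, 7 of 9 with 0 lower (7 and 1 adjusted over the list alone; mean 0.86, chips 0.92, 0.77 and 0.91, adjusted p = 9.3e-05), led by Apoc1 (2.98 ± 0.07) and the sterol regulator Srebf1 (1.32 ± 0.11). Cholesterol biosynthesis genes had 0 of 16 higher and 7 lower (0 and 9 adjusted over the list alone; mean -0.22, chips -0.18, -0.26 and -0.20, adjusted p = 0.0188; adjusted p = 0.0798 with an estimated correlation), among them mevalonate kinase, Mvk (-0.58 ± 0.11). That call was lost without TGF-β replicate 2 (adjusted p = 0.0718).

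Chemokine and cytokine receptors had 10 of 17 higher and 0 lower with TGF-β, also over the list alone (mean 0.55, chips 0.53, 0.53 and 0.61, adjusted p = 2.9e-05), with Cxcr4 up by 1.48 ± 0.10 and the TGF-β receptor Tgfbr1 by 0.79 ± 0.08. With genes below background in 1 group at their bound, the median went from 0.48 to 0.40 for these receptors, 0.66 to 0.53 for homeostatic genes and 0.78 to 0.64 for TGF-β targets. Without background correction the means of these 3 lists were 0.40, 0.51 and 0.63. Lysosomal genes had 14 of 26 higher and 2 lower, also over the list alone (mean 0.18, chips 0.19, 0.18 and 0.16, adjusted p = 0.0152), such as the cathepsins Ctss (0.87 ± 0.16) and Ctsd (0.81 ± 0.13), with a mean of 0.00 under scaling by the median alone, 0.19 above the median of all genes. Oxidative phosphorylation genes had 0 of 32 higher and 11 lower, also over the list alone (mean -0.15, chips -0.16, -0.12 and -0.17, adjusted p = 0.0111), with cytochrome c, Cycs, lower (-0.71 ± 0.07; another probe -0.24, adjusted p = 0.1001).

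Lists not called with TGF-β still held members that changed. Of 17 cytokine and chemokine genes 2 rose and 6 fell, also over the list alone (adjusted p = 0.3247); Cxcl16 rose at least 2.88-fold and Tnf by 0.70 ± 0.11, while Ccl4 fell (-1.03 ± 0.12). Of 16 pattern recognition receptors 3 rose and 5 fell, also over the list alone (adjusted p = 0.2084), with Tlr2 higher (1.67 ± 0.12) and Clec7a at least 2.61-fold lower. Of 19 alternative activation genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.8439), with a mean of 0.03 and a test pointing down. Egr2, a transcription factor gene, rose (1.85 ± 0.28), whereas Mgl2 (-1.05 ± 0.08) and Mrc1 (-0.61 ± 0.08) fell. Arg1 was below background on all TGF-β and untreated arrays.

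**Figure D3:**
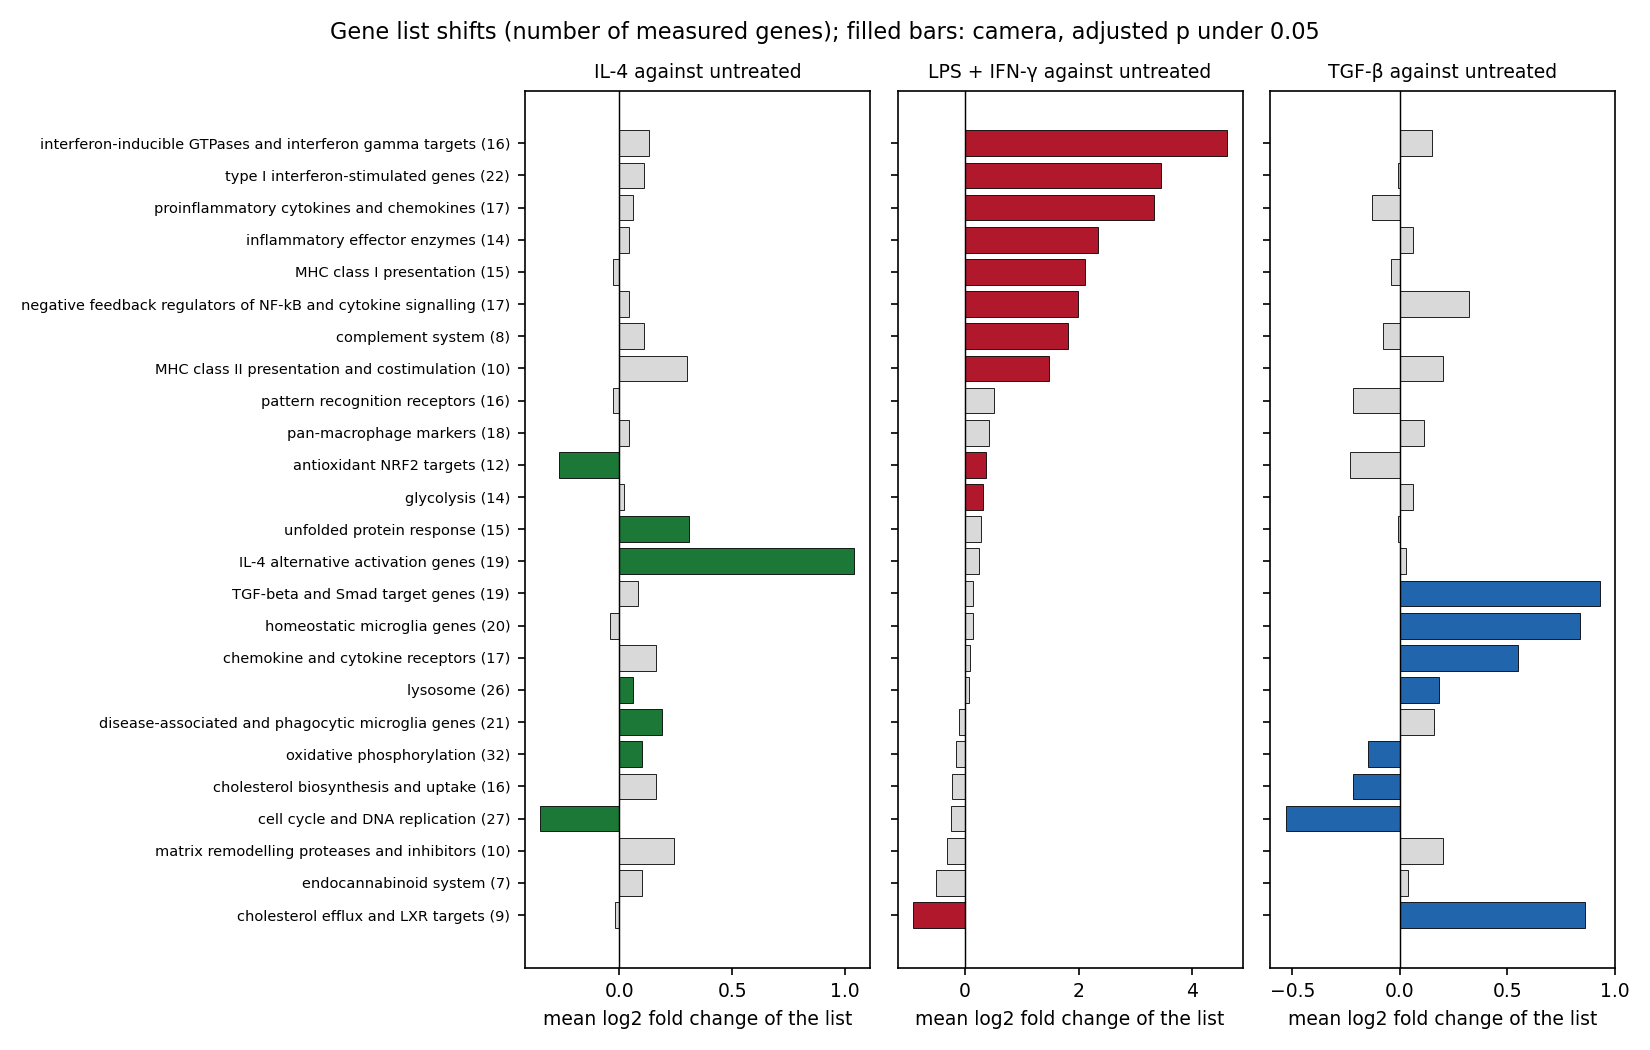
Mean log2 fold change of each gene list against untreated, by treatment, with the number of measured genes in brackets and a separate axis range per panel. Filled bars are lists called by camera at an adjusted p under 0.05, 7 with IL-4, 11 with LPS/IFN-γ and 8 with TGF-β.

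Set against IL-4, LPS/IFN-γ gave 4347 called genes (1839 higher, 2508 lower), 850 of them at least 2-fold, and 4488 with chip as a block. The highest by fitted value were Gbp2 (log2 fold change 9.09 ± 0.15), Serpina3f (at least 246-fold), Gbp3 (7.80 ± 0.13), Cxcl10 (at least 125-fold) and Ccl5 (7.49 ± 0.12). The lowest Gbp2 probe gave 2.67, and Gbp3 was above background on 2 of 3 IL-4 arrays. The genes with the lowest values were Ankrd37 (-4.96 ± 0.12), Lipn (-4.50 ± 0.13), Cytip (-4.45 ± 0.21), Klk1b11 (-3.81 ± 0.15) and Ang2 (-3.56 ± 0.15). Lipn and Ang2 were above background on only 1 of 3 LPS/IFN-γ arrays and Ankrd37 on 2 of 3, so these sizes rest on values near background. Against TGF-β, LPS/IFN-γ gave 4769 called genes (1996 higher, 2773 lower), 1029 at least 2-fold, and 4893 with chip as a block. The same interferon-induced genes led it, with Gbp2 at least 576-fold, Ccl5 at least 275-fold, Serpina3f at least 243-fold, Gbp3 at least 225-fold and Cxcl10 at least 123-fold higher. The lowest Gbp2 probe gave a log2 fold change of 2.59. Apoc1 (at least 22.3-fold), Itgb5 (at least 17.4-fold), Myo7a (at least 14.7-fold), Olfml3 (at least 12.4-fold) and Apoc4 (at least 6.90-fold) were lower.

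IL-4 and TGF-β differed in 2606 genes (1184 higher and 1422 lower with IL-4), 302 of them at least 2-fold, and in 2704 with chip as a block. Gas7 was at least 24.2-fold and Klk1b11 at least 18.9-fold higher with IL-4, Arg1 at least 5.15-fold, Cd74 by 4.56 ± 0.15 and Cish by 3.56 ± 0.40. Sgk1 (at least 24.7-fold) and Olfml3 (at least 13.3-fold) were lower with IL-4 than with TGF-β, as were Skil (-4.50 ± 0.22), Myo7a (-4.13 ± 0.16) and Itgb5 (-4.09 ± 0.19). Myo7a was above background on 1 of 3 IL-4 arrays, Itgb5 on 2 of 3, and Cish on 2 of 3 TGF-β arrays. The 30 named calls between treatments (10 per comparison) were all made with chip as a block too. In 4634, 4971 and 3837 of all 8561 genes the 3 arrays of 1 treatment did not overlap the 3 of the other, in the order given, which chance gives in 10% of genes.

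The responses to IL-4 and TGF-β overlapped more than the counts alone would give. Both raised 196 genes, against 95 expected from the counts of each, and both lowered 265 against 103, the cell cycle genes Aurkb and Tk1, picked as examples after their values were seen, among the latter. With separate untreated arrays for each treatment the counts were 99 against 50 and 135 against 44 on average over 20 splits. LPS/IFN-γ and TGF-β both raised 450 genes (362 expected) and both lowered 697 (558 expected), while IL-4 and LPS/IFN-γ shared 136 (104) and 177 (185). Calls in opposite directions exceeded their expectation for IL-4 and LPS/IFN-γ, with 217 genes higher with IL-4 and lower with LPS/IFN-γ (165 expected) and 179 the reverse, an even larger excess in proportion. For LPS/IFN-γ and TGF-β they were 317 (350) and 627 (579), and for IL-4 and TGF-β 80 (92) and 100 (107), the first treatment higher in the first count of each. All 3 treatments called 454 genes, of which 63 rose and 84 fell in all 3; 2436 were called in none. Across genes, fold changes correlated at 0.179 for IL-4 and TGF-β, 0.051 for LPS/IFN-γ and TGF-β, and 0.037 for IL-4 and LPS/IFN-γ (Pearson; Spearman 0.274, 0.077 and 0.043). Genes are not independent, and shared untreated arrays alone gave 0.332 to 0.333 in simulations without any effect. The observed covariances, 0.0203, 0.0161 and 0.0072, exceeded the simulated 0.0049.

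Of 20 pan-macrophage markers 18 were measured, 17 of them above background in untreated cells, with a median level of 10.20. Marco (5.16) was the exception, and the list was not called with IL-4 (adjusted p = 0.7927), LPS/IFN-γ (0.2778) or TGF-β (0.4352). Fewer markers of other cell types were measured. Of the stem cell markers 1 of 14 was measured (Pou5f1, 5.42), of the fibroblast markers 1 of 15 (Acta2, 6.28), of the granulocyte markers 1 of 15 (S100a8, 6.77) and of the lymphocyte markers 0 of 10. Counted by group, Pou5f1 was above background in no group, and Acta2 only in untreated and LPS/IFN-γ cells. Neuronal markers had 2 of 14 measured (Eno2, 10.21, and Elavl4, 6.26), astrocyte markers 3 of 10 (Aldoc, 11.91, Slc1a2, 7.34, and Aldh1l1, 5.46), oligodendrocyte markers 1 of 9 (Cnp, 7.03), endothelial markers 2 of 10 (Vwf, 7.77, and Eng, 5.84) and dendritic cell markers 4 of 12 (Itgax highest, 7.64). Eno2 and Aldoc encode glycolytic enzymes. Some of them, chosen after their values were seen, moved with treatment. S100a8 fell with IL-4 and rose with LPS/IFN-γ (0.91 ± 0.13) and TGF-β (1.78 ± 0.13), and Eno2 rose with LPS/IFN-γ (0.69 ± 0.09) and TGF-β (0.60 ± 0.09), while Elavl4, the other measured neuronal marker, fell with both (-0.44 ± 0.17 and -0.56 ± 0.17). Both measured endothelial markers rose with TGF-β (Vwf 1.66 ± 0.11, Eng 0.44 ± 0.11) and fell with LPS/IFN-γ (Vwf -0.88 ± 0.11, Eng at least 1.04-fold), too few genes for a list test. Acta2, a smooth muscle actin, rose with LPS/IFN-γ (0.78 ± 0.11) and fell with IL-4 (-0.52 ± 0.11) and TGF-β (-0.59 ± 0.11). The sizes of these falls rest on values near background.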

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

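The tests of LPS/IFN-γ replicate 3, the chip and scaling tests of the cell cycle genes and the test of the choice of scaling behind the LPS/IFN-γ calls were chosen only after the result was seen.

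Interferon-γ targets were higher in LPS/IFN-γ replicate 3 than in both other arrays of its group for 13 of 16 genes (mean deviation 0.98), Cxcl9 among them, and so were 9 of 10 MHC class II genes (0.74), 13 of 19 alternative activation genes (0.71), 12 of 17 feedback regulators (0.71), 11 of 17 cytokines (0.72) and 13 of 19 TGF-β targets (0.48). Of 22 type I interferon-stimulated genes 12 were lower than in both others (mean -0.17), and 145 genes in all were at least 2-fold off, 99 higher and 46 lower. Low signal and an effect of chip 3 were argued against only for genes above background elsewhere: for 104 of them the median share of the deviation seen on untreated replicate 6, also of low signal, was 1.5%, and for 99 the share on the other arrays of the chip was -0.9%. For the remaining 41 and 46 genes, Cxcl9 among them, arrays of other groups cannot show a deviation, so low signal and chip cannot be told apart from a response there. A stronger response to the whole treatment cannot be told apart from an uneven one, since 64.9% of the 698 genes changed at least 2-fold lay further from untreated in it and 22.6% nearer.

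Cell cycle genes were lower with IL-4 and with TGF-β, with a list mean per array of 10.35 to 10.43 and 10.20 to 10.23 against 10.70 to 10.77 in untreated cells; LPS/IFN-γ arrays, at 10.46 to 10.53, were also below untreated, though that list was not called. Chance levels of single untreated arrays were argued against, because the smallest list mean with separate untreated arrays was 93.3% of the full one. A level shared by all untreated arrays would stay in every such part, so this test cannot speak to it. Within chips the mean was no nearer to 0 than -0.33. Every IL-4 and TGF-β array lay below every untreated array, which fixed this outcome in advance, so it cannot speak to differences between chips. Scaling between arrays was argued against, with a mean of at most -0.31 relative to all genes. A biological explanation such as slower growth was not tested, since cell numbers and growth rate were not measured, and the cause stays open.

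More genes were called lower than higher with LPS/IFN-γ, 2933 against 1837. With cyclic loess in place of quantile normalization 49.9% of the calls were higher, and with scaling by the median alone 33.0%, so the imbalance depended on the choice of scaling. Quantiles fitted without the 1211 probes changed at least 2-fold gave 48.2%, a rise just short of the size set beforehand for this explanation. A general lowering of transcripts and a shift of the quantiles by strongly changed probes cannot be told apart here, because no measure of total RNA per cell was used.

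Over the genes of the naming rule, the other genes named and the list means, 19 of 222 values had 1 untreated array far from the other 5, and chance gives such a value in about 1 in 20 groups. Untreated replicate 1 was low for Apoe (12.72; others from 13.04), Fabp5 (8.61; from 8.87) and Gas6 (12.08; from 12.25) and high for Casp1 (12.69; up to 12.56), Cnp (7.44; up to 7.05) and Tapbpl (6.25; up to 5.98). Untreated replicate 2 was high for Adam8 (7.56; up to 7.35) and Ftl1 (14.86; up to 14.66) and low for Elavl4 (6.01; from 6.23). Untreated replicate 3 was low for Ccl5 (5.82; from 6.04) and high for Cdc20 (11.50; up to 11.29) and Chst10 (9.14; up to 9.02). Untreated replicate 6 was high for H2-T23 (10.54; up to 10.29), Nos2 (5.73; up to 5.02) and Naaa (6.13; up to 5.82) and low for Skil (5.18; from 5.92). Untreated replicate 5 was low for Mthfd2 (11.82; from 11.92) and high for Slc10a6 (8.19; up to 8.05). The mean of the endocannabinoid list was high in untreated replicate 4 (9.15; up to 9.07).

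Probes without 1 current gene symbol, which no comparison used, also responded. With IL-4, 148 of them were called (78 higher, 70 lower), with LPS/IFN-γ 864 (382 and 482) and with TGF-β 560 (253 and 307).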

How the results depend on the processing

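The quantiles fitted without strongly changed probes were an alternative chosen after seeing the data; they gave 4549 calls with LPS/IFN-γ, and the other alternatives were planned. Of the named genes' values under the settings other than leaving out an array or blocking by replicate, 904 of 952 with IL-4, 1265 of 1302 with LPS/IFN-γ and 1139 of 1162 with TGF-β kept direction and side of the threshold; 27, 17 and 8 lost a call and 21, 19 and 13 gained one. Direction reversed 3 times. Rrm2 with LPS/IFN-γ gave 0.146 (adjusted p = 0.4137) on another probe. Srebf2 with TGF-β (0.085, not called) gave -0.242 (0.0053) as the mean of its probes and -0.569 (4.8e-05) on another probe. Depth limits dim genes, since signal near background was compressed.

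With IL-4, 345 genes were called with median scaling only and 1767 in the authors' table, whose tests count removed chip terms as free. Asking for at least 2-fold as well leaves fewer calls by construction: 54, 698 and 235 against untreated, 850 for LPS/IFN-γ against IL-4, 1029 for LPS/IFN-γ against TGF-β and 302 for IL-4 against TGF-β. An estimated correlation left 7 lists called with LPS/IFN-γ; fry, which does not compare a list with other genes, called 21 with LPS/IFN-γ and 17 with TGF-β. In the authors' table the IL-4 and LPS/IFN-γ responses correlated at 0.019 with 225 shared higher and 397 shared lower calls, and those to IL-4 and TGF-β at 0.203 with 342 and 498. Without a filter on dim probes IL-4 and LPS/IFN-γ gave 0.057 with 110 shared lower calls, and LPS/IFN-γ and TGF-β 0.063. With the controls split, IL-4 and LPS/IFN-γ gave 0.014, 80 and 76, IL-4 and TGF-β 0.135, 99 and 135, and LPS/IFN-γ and TGF-β 0.037; fewer controls per fit lower these counts. Beyond that, the cause was not tested.

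Leaving out 1 array gave 594 (without IL-4 replicate 1) to 1410 (without LPS/IFN-γ replicate 3) calls with IL-4, with 603 without IL-4 replicate 3, 4125 to 4794 with LPS/IFN-γ and 2710 to 3681 with TGF-β. Between treatments it gave 3894 to 4364, 4347 to 4789 and 2050 to 3023. Lists called ranged over 5 to 9, 9 to 12 and 7 to 9. Named genes lost a call in 44 of 1020 such values with IL-4, 8 of 1395 with LPS/IFN-γ and 10 of 1245 with TGF-β.

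With a replicate block the counts were 459 for IL-4, 4037 for LPS/IFN-γ and 2585 for TGF-β, and 258 named values kept their side, 14 lost it and 2 gained it. The numbers follow the listed order and were not taken as pairs. Deviations of same-numbered treated arrays correlated between -0.186 and 0.357 (median 0.156, 5 of 9 over 0.1). Over all groups, the median was 0.165 for the same number and -0.041 for different numbers, so a weak shared part, which chip also follows for treated arrays, stays open; the block also costs degrees of freedom and leaves 3 untreated arrays without a partner.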

Other observations

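The counts of splits were planned, and the gene lists below were picked for description after their results were seen.

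Genes of the endocannabinoid system, lipid signals that microglia make and degrade, were not called as a list of 7 measured genes with any treatment (adjusted p = 0.5355 with IL-4, 0.0668 with LPS/IFN-γ, 0.7648 with TGF-β). With LPS/IFN-γ 4 fell and 0 rose, also over the list alone, and without LPS/IFN-γ replicate 3 the list was called (adjusted p = 0.0128). Daglb, which makes 2-arachidonoylglycerol, fell (-1.17 ± 0.08), as did Abhd12, which degrades it (-1.14 ± 0.11), the cation channel gene Trpv2 (-0.63 ± 0.09) and Naaa (at least 1.01-fold). IL-4 raised Trpv2 (0.83 ± 0.09) and TGF-β raised Abhd12 (0.52 ± 0.11; 0.29 with scaling by the median alone, adjusted p = 0.2464). The cannabinoid receptor gene Cnr2 was above background on 0 arrays.

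Matrix proteases and their inhibitors likewise held called members without a called list (adjusted p = 0.1996, 0.7731 and 0.6310 for IL-4, LPS/IFN-γ and TGF-β). With LPS/IFN-γ the list mean was -0.32 and the median 0.01. Timp2, an inhibitor of metalloproteases, fell with LPS/IFN-γ (-2.07 ± 0.10) and rose with TGF-β (0.55 ± 0.10). Mmp12, a macrophage elastase, fell at least 2.36-fold with LPS/IFN-γ, and Adam8 fell by 0.76 on the log2 scale. TGF-β raised Mmp14, a membrane-bound protease, at least 1.40-fold, and Plau, the urokinase gene, by 1.89 ± 0.20. Plau also rose with LPS/IFN-γ (1.07 ± 0.20) and with IL-4 (0.85 ± 0.20), the last call being lost without IL-4 replicate 1 (0.74, adjusted p = 0.0652). Complement genes with TGF-β had a mean of -0.08 and a median of 0.17 (adjusted p = 0.8439).

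For the counts of called genes against untreated, 1 of 84 splits, the real one, gave as many with each treatment. It gave 1024, 4770 and 3318 calls against highest others of 2, 1 and 1. This argues only against a chance arrangement of these arrays. The other splits mix treated and untreated arrays, so they do not show counts without any effect. Chance between cultures cannot be judged, because the labels do not give the cultures. For the counts of called lists, 3 of 84 splits gave as many with IL-4 (7 lists, highest other 7). With LPS/IFN-γ 11 of 84 did (11 lists, highest other 13), and with TGF-β 13 of 84 (8 lists, highest other 9). By the share set beforehand this argued against chance with IL-4 only. Other splits that keep treated arrays together carry part of the real effect, so this count cannot decide how far lists arise by chance. The smallest adjusted p of a list was lower in the real split each time, 7.7e-15, 2.9e-25 and 6.6e-12 against 6.4e-12, 1.7e-12 and 3.7e-09 in any other. Between treatments, 10 splits are too few; the real split called 4347, 4769 and 2606 genes and the highest other 0, 1 and 0.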
